A study of Coturnix japonica with 15 samples.

How the data were processed

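RNA of the left lobe of the liver was sequenced from Japanese quail (Coturnix japonica) embryos at embryonic day 9. Each egg had received 10 µl of dosing solution in its air cell before incubation at 37 °C and 60% humidity. The solvent was DMSO, and ethinylestradiol, a synthetic oestrogen, was given at 3.33 or 33.3 µg per g of egg. Each of the 3 groups held 5 libraries, 15 in all. The labels do not say whether each library came from a separate embryo.

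The authors quantified the reads with kallisto, whose version, transcript index and genome build are not given in the sources used here. The deposited table holds estimated counts (expected counts) per transcript with no normalization, and each of its 47418 transcript entries is named by an NCBI gene ID. The 21 values of 7 digits, in 4 genes, are written with at most 3 significant digits. All columns of per-sample values were used.

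Transcript values were summed per gene ID and rounded to whole numbers, which gave 20308 gene IDs. Of these, 18900 (93.1%) matched the gene table for the Coturnix japonica reference, 12972 with a symbol and 5928 with only a locus number. The 1408 IDs without a match held a median of 0.51% of the counts of a library. Order along the chromosomes was taken from that reference assembly, which may differ from the one behind the transcript index, so no coordinates are given. Library totals ran from 21715273 to 54591426 estimated counts, with a median of 28086522. Intervals and detection floors cover counting error only, because reads without molecular identifiers are not independent molecules. A floor was set at 3 counts over a group.

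The comparisons, the tests, the 25 gene lists, the rule for naming genes and the alternative settings were fixed before the data were examined. edgeR 4.0.16 was run in R 4.3.3 with filterByExpr by group, TMM normalization and the robust quasi-likelihood F-test, with all 15 libraries in 1 model of group. This tested 14508 genes, with a common biological coefficient of variation of 0.26. Contrasts were each dose against solvent and 33.3 against 3.33 µg/g; a further fit took the dose rank (0, 1 and 2) as a number. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05 and no threshold on the fold change. Standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. Values per library are counts on TMM-scaled totals set to 1e+06 (CPM), given as mean ± SD of 5 libraries.

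Gene lists with at least 5 tested members, 24 of the 25, were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Fry values are those of its directional test unless its mixed test, which takes changes in either direction, is named. The number of members passing when p-values were adjusted over the list alone is given beside the number passing over all genes tested.

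The genes named for each comparison with solvent were, among genes with a symbol, an adjusted p under 0.05 and a mean of at least 1 CPM in the higher group, the 10 with the largest rise and the 10 with the largest fall. For the comparison between the doses, in which fewer than 5 genes passed, the 5 with the smallest p were named. Every tested member of the yolk precursor list, the oestrogen receptor gene ESR1 and, from each other list, up to 4 members with the smallest p were added, and not all of these are described. The text also names some genes that have only a locus number and, as neighbours or for the dose trend, genes chosen after their values were seen.

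The pipeline was tested on simulated data in which 200 of 14508 genes were changed in each comparison. Changes of 4-fold were recovered for 97% of genes at 33.3 µg/g against solvent, 89.4% at 3.33 µg/g against solvent and 90.9% between the doses. Changes of 2-fold were recovered for 64.2%, 68.7% and 59.7%, and changes of 1.5-fold for 32.8%, 37.3% and 29.9%. False calls made up 4.4%, 3% and 5.5% of the calls. In a simulated comparison with independent genes 1 raised list was called and 0 of 24 unchanged lists were. Other groupings of the real libraries gave a median of 5 or 6 lists.

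The alternatives were RLE factors, library totals only, 2 other low-count filters, DESeq2 1.42.0, limma-voom and a replicate block. Further ones were the mean of erythroid markers or of chromosome Z genes as a covariate, a fit to only the 2 groups compared, a threshold on the fold change, an adjusted p under 0.1, and each library left out in turn. Replicate numbers did not pair the libraries: of 15 pairs with the same number, 1 had a correlation of residuals over 0.1, and 0 libraries correlated best with their own number. No pair of replicates was a copy of another, the lowest chi-square per degree of freedom over 30 pairs being 26.2. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.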

Results

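Liver RNA was compared between quail embryos at embryonic day 9 whose eggs had received solvent, 3.33 µg/g ethinylestradiol or 33.3 µg/g ethinylestradiol, with 5 libraries per group. Total estimated counts were 21726195 to 32140126 in the solvent libraries, 22075439 to 37046558 at 3.33 µg/g and 21715273 to 54591426 at 33.3 µg/g. The comparisons asked how the embryonic liver transcriptome responded to an oestrogen given before incubation, and whether the response differed between the doses. Albumin transcripts took 9.71% to 13.3% of the counts in 13 libraries. They took 4.85% (95% Wilson interval 4.84% to 4.86%) in 3.33 µg/g replicate 4 and 5.87% (5.87% to 5.88%) in 33.3 µg/g replicate 1, for counts that the file writes with 3 significant digits.

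At 33.3 µg/g, transcripts of egg yolk transport rose. APOB, the structural protein of the lipoproteins that carry lipid to the yolk, was at 6918 ± 752 CPM with solvent and 19698 ± 2248 CPM at 33.3 µg/g (log2 fold change 1.51, SE 0.15, adjusted p = 0.000102). RBP4, which carries retinol in plasma, rose from 1072 ± 81.3 to 1745 ± 328 CPM (log2 fold change 0.70, SE 0.13, adjusted p = 0.0115). Both genes were higher in 5 of 5 treated libraries than in every solvent library. ZP1, an egg coat protein that the avian liver makes under oestrogen, averaged 112 ± 22.5 CPM against 10.9 ± 19.1 CPM and did not pass (log2 fold change 3.37, SE 0.80, adjusted p = 0.0586). The solvent mean of ZP1 rested on replicate 3, at 45.1 CPM against 1.45 to 3.06 CPM in the other solvent libraries, and without that library ZP1 passed (log2 fold change 5.53, adjusted p = 7.15e-06). The oestrogen receptor gene ESR1 was at 22.3 ± 10.8 CPM with solvent and 16.2 ± 3.2 CPM at 33.3 µg/g (adjusted p = 0.561).

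The largest rises among genes with a symbol were in transcripts scarce with solvent. NPTXR, a neuronal pentraxin receptor, went from 1.32 ± 0.559 to 99.5 ± 70.2 CPM (log2 fold change 6.25, SE 0.68, adjusted p = 0.000191). CORIN, a membrane protease, went from 0.426 ± 0.43 to 27.5 ± 13.2 CPM (5.90, SE 0.64, adjusted p = 0.000191). SPATA1 went from 2.04 ± 0.775 to 50.8 ± 23 CPM (4.65, SE 0.39, adjusted p = 2.74e-05). ELOVL2, an elongase of polyunsaturated fatty acids, rose by a log2 fold change of 6.65 (SE 1.19, adjusted p = 0.0102) and was above every solvent library in 4 of 5 treated libraries. FAXDC2 (6.07), GAREM2 (5.46) and the potassium channel gene KCNK9 (3.94) rose in 5 of 5 libraries, as did CKMT2 (5.32), a mitochondrial creatine kinase, and HHIPL2 (3.96). BEST3, a chloride channel gene, had 0 counts in the solvent libraries and was at least 113-fold higher at 33.3 µg/g, set against a floor of 3 counts over the group, or at least 68.2-fold without 33.3 µg/g replicate 2. The BEST3 call ended without solvent replicate 1 (adjusted p = 0.0550), and the CKMT2 and HHIPL2 calls ended without any of solvent replicates 1, 2, 4 or 5 (adjusted p up to 0.0634 and 0.0772). With limma-voom ELOVL2 (adjusted p = 0.477), FAXDC2 (0.304), CKMT2 (0.290) and HHIPL2 (0.182) did not pass, nor with a replicate block did BEST3 (0.121), ELOVL2 (0.0550) and HHIPL2 (0.0572). Without solvent replicate 3 the log2 fold change of ELOVL2 was 7.39, without replicate 1 that of CORIN 6.84, without replicate 2 that of KCNK9 5.10 and without replicate 5 that of FAXDC2 6.98. Without 33.3 µg/g replicate 1 that of ELOVL2 was 5.63, and without replicate 5 that of HHIPL2 3.19. Loci without a gene name also rose, and a pair of them at a high level is described. Others rose further, among them LOC107314278 (8.88, adjusted p = 0.000362) and LOC107319112 (8.78, adjusted p = 8.81e-05). LOC107317574 rose by 10.05 (adjusted p = 0.000751) but did not pass with limma-voom (0.134). LOC107317565 averaged 54.1 ± 103 CPM with solvent and 11684 ± 7078 CPM at 33.3 µg/g (log2 fold change 7.76, SE 1.38, adjusted p = 0.0101). LOC107319873 averaged 44.3 ± 84.6 and 11057 ± 6137 CPM (7.97, SE 1.45, adjusted p = 0.0117). Both solvent means rested on replicate 3, at 238 and 195 CPM against 1.13 to 16.3 and 0.347 to 13.8 CPM in the other solvent libraries. Without that library the log2 fold changes were 10.47 and 10.72. The fit to 2 groups ended the call of LOC107319873 (adjusted p = 0.0519).

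**Figure D1:**
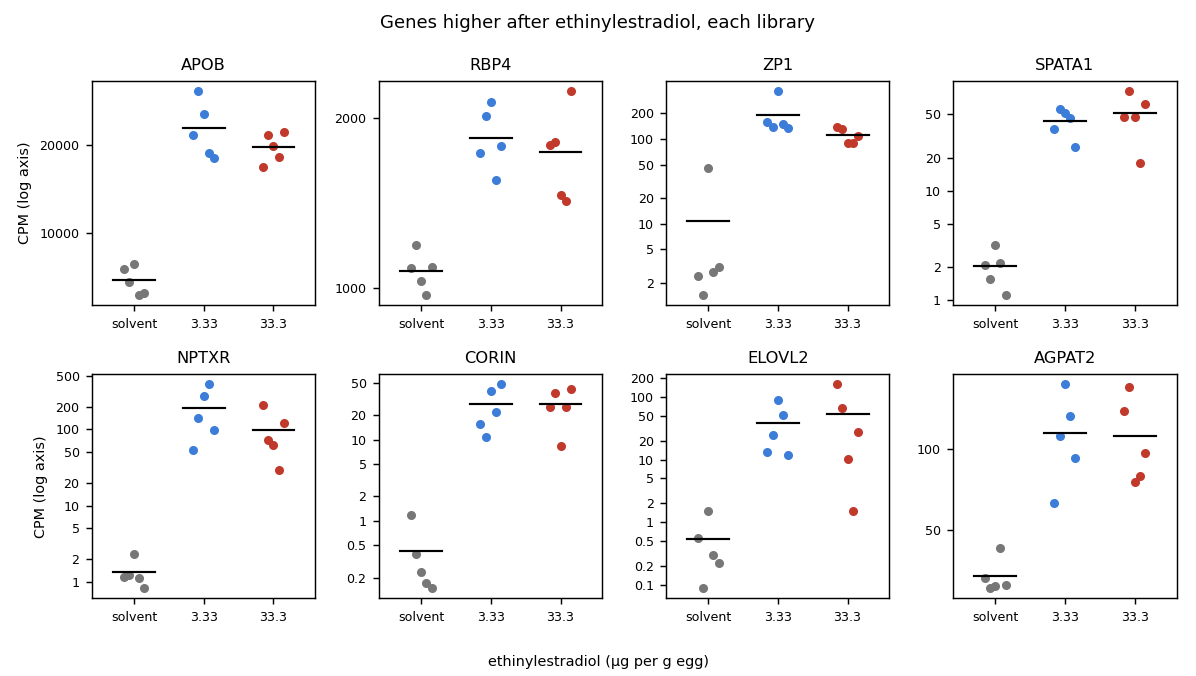
CPM on a log axis for 8 genes in each library, by ethinylestradiol dose in µg per g of egg; each point is 1 library of 5 per group and each line a group mean. APOB averaged 6918 CPM with solvent and 19698 CPM at 33.3 µg/g, and solvent replicate 3 stood apart for ZP1 at 45.1 CPM; ZP1 passed the test at 3.33 µg/g and not at 33.3 µg/g.

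Falls at 33.3 µg/g were fewer and smaller. WNT2B, a secreted Wnt ligand, went from 11.6 ± 1.95 to 5.12 ± 1.04 CPM (log2 fold change −1.18, SE 0.20, adjusted p = 0.00824). The receptor gene GPR142 went from 2 ± 0.817 to 0.483 ± 0.143 CPM (−2.04, SE 0.37, adjusted p = 0.0108), and PRDM6 from 3.89 ± 0.655 to 1.57 ± 0.393 CPM (−1.31, SE 0.25, adjusted p = 0.0170). The fibrinogen chain genes FGG, from 4300 ± 1122 to 2077 ± 452 CPM, and FGB, from 5498 ± 1465 to 2661 ± 643 CPM, each fell by 1.05 on the log2 scale (adjusted p = 0.0410 and 0.0454). ADAMTS17 (−1.43), PLA2G3 (−1.19), LTK (−0.99), KIAA0040 (−0.94) and ZBTB42 (−0.88) also passed. All of these genes were lower in 5 of 5 treated libraries than in every solvent library. Leaving out 1 library ended the calls of 7 of them, with adjusted p up to 0.119 for FGG, 0.129 for FGB, 0.0704 for ADAMTS17, 0.127 for PLA2G3, 0.106 for LTK, 0.0984 for KIAA0040 and 0.0679 for ZBTB42. Each of the 5 solvent libraries, each of the 5 libraries at 33.3 µg/g and replicates 1, 4 and 5 at 3.33 µg/g ended at least 1 of these calls. With a replicate block FGG (0.0983), FGB (0.1055), ADAMTS17 (0.0970), PLA2G3 (0.0738), KIAA0040 (0.0712) and ZBTB42 (0.0675) did not pass, nor with limma-voom did FGG (0.0515), FGB (0.0541) and LTK (0.0846). The erythroid covariate ended the calls of FGG (0.0543) and FGB (0.0625), and the fit to 2 groups those of KIAA0040 (0.0636) and ZBTB42 (0.0540). Without the 2 libraries of low albumin share FGG (0.105), FGB (0.107), PLA2G3 (0.115), LTK (0.116) and ZBTB42 (0.0574) did not pass.

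In the lists fixed for lipid metabolism, 3 of 19 tested genes of fatty acid and triglyceride synthesis rose and 0 fell. These were ELOVL2, AGPAT2, which makes phosphatidic acid (33.7 ± 5.22 to 112 ± 41.2 CPM, log2 fold change 1.74, SE 0.27, adjusted p = 0.00305), and the elongase gene ELOVL5 (0.89, SE 0.18, adjusted p = 0.0206). ELOVL5 did not pass without solvent replicate 1 or 4 or 33.3 µg/g replicate 1 or 3 (adjusted p up to 0.0688). Adjusted over the list alone, 7 genes rose. The list rose as a set (median log2 fold change 0.17, adjusted p = 1.77e-05; adjusted p = 0.0371 with an estimated correlation). The yolk precursor list, with 5 of 12 members tested, held 2 genes that rose (3 adjusted over the list alone). It rose as a set (median 0.70, adjusted p = 4.75e-08; adjusted p = 0.00227 with an estimated correlation). MTTP (−0.13, adjusted p = 0.851) and the transferrin gene TF (−0.16, adjusted p = 0.888) did not pass. The vitellogenin genes of that list have no entry under their symbols in the gene table. Of 19 tested genes of cholesterol synthesis and uptake, 0 passed over all genes and 6 rose adjusted over the list alone. That list rose as a set (median 0.34, 18 of 19 values above 0, adjusted p = 2.17e-07; adjusted p = 0.110 with an estimated correlation).

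The list of endoplasmic reticulum stress and the integrated stress response rose as a set at 33.3 µg/g (median 0.24, adjusted p = 5.86e-06; adjusted p = 0.424 with an estimated correlation). Of its 24 tested genes 2 rose over all genes and adjusted over the list alone. These were HERPUD1, of protein degradation from the reticulum (0.69, SE 0.15, adjusted p = 0.0335), and the serine synthesis gene PSAT1 (1.56, SE 0.35, adjusted p = 0.0428). Both calls ended without any of 33.3 µg/g replicates 2 and 3 and solvent replicates 2, 3, 4 and 5. That of HERPUD1 also ended without 33.3 µg/g replicate 1 or 5 or 3.33 µg/g replicate 3 (adjusted p up to 0.103). That of PSAT1 also ended without solvent replicate 1 or 3.33 µg/g replicate 1, 2 or 5 (adjusted p up to 0.1245). HERPUD1 and PSAT1 did not pass with limma-voom (0.0760 and 0.0811) or a replicate block (0.0728 and 0.0958). The fit to 2 groups ended both calls as well (0.0752 and 0.109). Hepatocyte plasma proteins fell as a set (median −0.21, adjusted p = 0.000281; adjusted p = 0.633 with an estimated correlation), with FGG and FGB the 2 of 27 tested genes passing; adjusted over the list alone 3 fell and 2 rose. The score of this list in 33.3 µg/g replicate 1, the library with the lower albumin share, was 8.93 mean log2 CPM against 9.57 to 9.78 in the other libraries of that dose. The plasma protein call ended without that library (adjusted p = 0.0571) and without the 2 libraries of low albumin share (0.0678).

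Fatty acid oxidation (median −0.18, adjusted p = 4.47e-05), cell cycle (median −0.21, adjusted p = 7.53e-06) and acute phase and interferon response (median −0.65, adjusted p = 0.00514) also fell as sets at 33.3 µg/g. With an estimated correlation these lists did not pass (adjusted p = 0.539, 0.633 and 0.633). None of their 19, 32 and 14 tested genes passed over all genes; adjusted over the list alone, 3 genes of fatty acid oxidation fell and 0 of the other lists changed. The acute phase call ended without solvent replicate 5 (adjusted p = 0.393). In the remaining lists the coactivator gene NCOA1 rose (0.65, SE 0.12, adjusted p = 0.0138). So did HSD17B12, of fatty acid elongation and steroid metabolism (0.43, SE 0.08, adjusted p = 0.0196), and the endocytic receptor gene CUBN (3.72, SE 0.74, adjusted p = 0.0201). NCOA1 did not pass without solvent replicate 1 (adjusted p = 0.0530), HSD17B12 without solvent replicate 1 or 3 (up to 0.0627), and CUBN without solvent replicate 1, 2, 4 or 5 or 33.3 µg/g replicate 2 (up to 0.0670). CUBN did not pass with limma-voom (0.211), nor HSD17B12 with a replicate block (0.0894). The fit to 2 groups ended the calls of NCOA1 (0.0533) and CUBN (0.0532).

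Over all 14508 genes tested with edgeR, 157 passed at 33.3 µg/g against solvent, 136 higher and 21 lower, and 1560 had an unadjusted p under 0.05 where chance gives 725. The median log2 fold change was 1.5 among the genes that rose and −0.94 among those that fell. Of the 157 genes, 34 have only a locus number or no symbol. The count was 93 without solvent replicate 1, with 84 higher, and 103 without solvent replicate 4. The number lower was 5 to 13 without solvent replicate 1, 2 or 4 or 33.3 µg/g replicate 1, 2, 3 or 5, and 35 and 39 without replicate 4 at 3.33 and at 33.3 µg/g. Changes of 1.5-fold were mostly not detectable, being recovered for 32.8% of simulated genes.

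At 3.33 µg/g the same members of the yolk list rose, with ZP1. APOB reached 22833 ± 5164 CPM (log2 fold change 1.72, SE 0.16, adjusted p = 2.50e-05), RBP4 1847 ± 233 CPM (0.78, SE 0.13, adjusted p = 0.00464) and ZP1 189 ± 98.9 CPM (4.13, SE 0.82, adjusted p = 0.0198). Each was above every solvent library in 5 of 5 libraries. The ZP1 call ended without solvent replicate 1, 4 or 5 or 3.33 µg/g replicate 3 (adjusted p up to 0.0543), and without solvent replicate 3 the log2 fold change of ZP1 was 6.29. In the fit to 2 groups ZP1 did not pass (0.0754). The list rose as a set (median 0.78, adjusted p = 1.04e-05; adjusted p = 0.0133 with an estimated correlation). Adjusted over the list alone 3 genes rose and 2 fell; over all genes MTTP (−0.45, adjusted p = 0.156) and TF (−0.53, adjusted p = 0.304) did not pass, nor did ESR1, at 17.4 ± 3.51 CPM (adjusted p = 0.566).

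NPTXR (192 ± 139 CPM, log2 fold change 7.20, SE 0.70, adjusted p = 6.00e-05), CORIN (27.1 ± 15.9 CPM, 5.88, SE 0.64, adjusted p = 0.000201) and SPATA1 (42.8 ± 12.2 CPM, 4.40, SE 0.39, adjusted p = 2.50e-05) rose at 3.33 µg/g as well. So did CKMT2 (7.02), GAREM2 (5.11), HHIPL2 (4.73), ELOVL2 (6.17) and FAXDC2 (4.69). BEST3 was at least 79.2-fold higher than the floor of 3 counts over the group. AANAT, an enzyme of melatonin synthesis, had 1 count in the solvent libraries and 228 at 3.33 µg/g, a ratio of 183 with a 95% counting interval of 32.5 to 7256. Without 3.33 µg/g replicate 4 the ratio was 99.3 (17.4 to 3961), and without solvent replicate 3 AANAT was at least 50.8-fold higher than that floor. The calls of BEST3 (0.0543) and ELOVL2 (0.0540) ended without solvent replicate 1, and that of AANAT without any 1 solvent library (up to 0.0674). The FAXDC2 call ended without solvent replicate 1, 2, 3 or 4 or 3.33 µg/g replicate 3 (up to 0.0609). With limma-voom ELOVL2 (0.335), FAXDC2 (0.332), CKMT2 (0.0967), HHIPL2 (0.0584), BEST3 (0.0604) and AANAT (0.0674) did not pass, nor with a replicate block did BEST3 (0.107) and AANAT (0.0701). LOC107317565 averaged 15099 ± 7035 CPM (8.13, SE 1.40, adjusted p = 0.00730) and LOC107319873 13248 ± 5626 CPM (8.23, SE 1.47, adjusted p = 0.00960). Without solvent replicate 3 these log2 fold changes were 10.84 and 10.98, and that of ELOVL2 was 6.91. Without solvent replicate 1 that of CORIN was 6.82, without replicate 5 that of FAXDC2 5.60, and without 3.33 µg/g replicate 2 that of CKMT2 6.07.

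At 3.33 µg/g CPT1A, which admits fatty acids to the mitochondrion, went from 923 ± 130 to 481 ± 144 CPM (log2 fold change −0.94, SE 0.20, adjusted p = 0.0254). CPT1A did not pass without solvent replicate 1, 3 or 4 or 3.33 µg/g replicate 2 or 3 (adjusted p up to 0.0704). At 33.3 µg/g CPT1A averaged 546 ± 106 CPM and did not pass (adjusted p = 0.0931), but passed without 3.33 µg/g replicate 4 (0.0276). Fatty acid oxidation fell as a set (median −0.33, 18 of 19 values below 0, adjusted p = 5.55e-08; adjusted p = 0.290 with an estimated correlation), with 2 of 19 genes passing and 7 adjusted over the list alone. The adhesion gene ALCAM (46.6 ± 7.7 to 21.1 ± 6.3 CPM, −1.14, SE 0.18, adjusted p = 0.00323) fell in 5 of 5 libraries. So did WNT2B (4.01 ± 1.18 CPM, −1.52, SE 0.21, adjusted p = 0.00116) and PLA2G3 (−1.44, SE 0.27, adjusted p = 0.0131). CALHM3 (−2.31), GPR142 (−1.80), PERCC1 (−1.62), SYT12 (−1.48), PRDM6 (−1.14) and TMEM181 (−0.96) passed too, GPR142 with 4 of 5 libraries below every solvent library. The CALHM3 call ended without 3.33 µg/g replicate 3 (adjusted p = 0.0530). The calls of GPR142 (up to 0.0622), PERCC1 (0.102), SYT12 (0.0775), PRDM6 (0.0804) and TMEM181 (0.112) each ended without any of 4 or more libraries. Among these were each solvent library, each library at 3.33 µg/g and replicates 2, 3 and 5 at 33.3 µg/g. With a replicate block CPT1A (0.0912), CALHM3 (0.0746), GPR142 (0.0654), PERCC1 (0.119), SYT12 (0.0973) and TMEM181 (0.109) did not pass, nor did TMEM181 with limma-voom (0.0624). The fit to 2 groups ended the calls of CPT1A (0.0510), GPR142 (0.0510), PRDM6 (0.0541) and TMEM181 (0.0581).

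**Figure D2:**
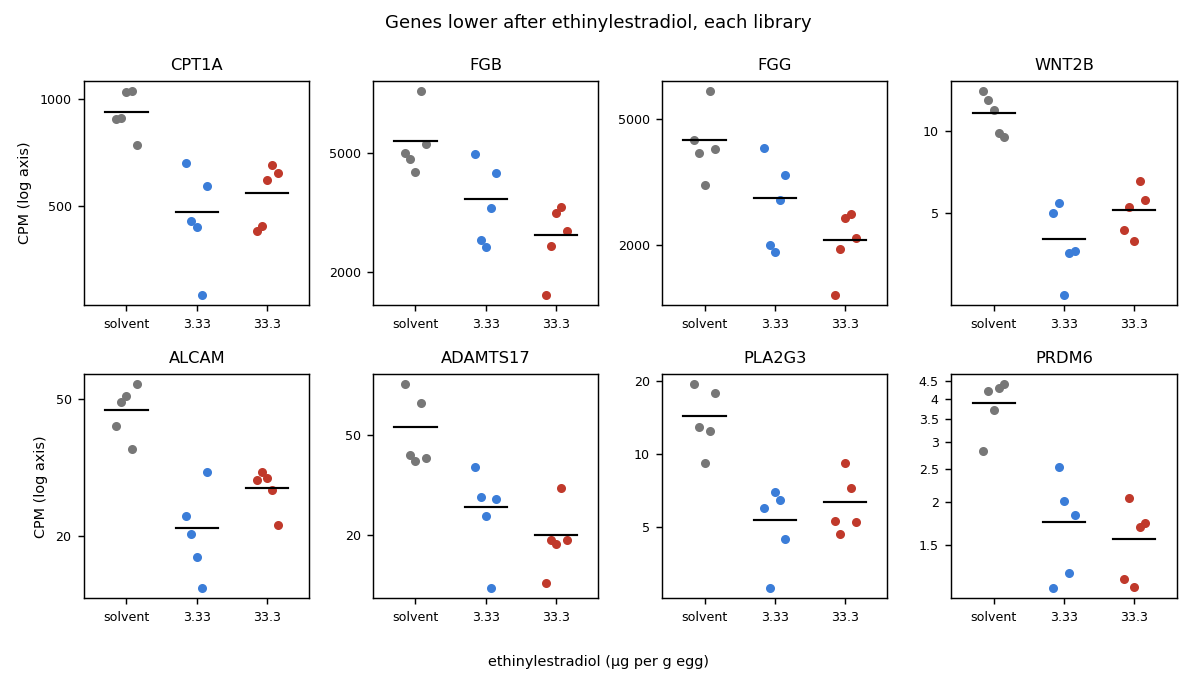
CPM on a log axis for 8 genes in each library, by ethinylestradiol dose in µg per g of egg; each point is 1 library of 5 per group and each line a group mean. CPT1A and ALCAM passed at 3.33 µg/g, FGB, FGG and ADAMTS17 at 33.3 µg/g, and WNT2B, PLA2G3 and PRDM6 at both; CPT1A averaged 923, 481 and 546 CPM across the 3 groups.

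Fatty acid and triglyceride synthesis rose as a set at 3.33 µg/g (median 0.36, adjusted p = 4.66e-05; adjusted p = 0.0602 with an estimated correlation). The 3 of 19 genes that rose were ELOVL2, AGPAT2 and LPIN1. AGPAT2 was at 115 ± 41.9 CPM (1.77, SE 0.27, adjusted p = 0.00240), and LPIN1, a phosphatidate phosphatase, rose further (3.56 ± 0.46 to 17.8 ± 12.8 CPM, 2.32, SE 0.44, adjusted p = 0.0142). LPIN1 did not pass with limma-voom (0.170) or a replicate block (0.0577). Adjusted over the list alone 8 rose and 1 fell. Macrophage and leukocyte markers rose as a set (median 0.69, adjusted p = 1.67e-05; adjusted p = 0.296 with an estimated correlation), with 13 of 14 values above 0 and 7 genes passing adjusted over the list alone. Over all genes 1 passed, the complement gene C1QB (8.16 ± 1.65 to 14.9 ± 4.02 CPM, 0.87, SE 0.18, adjusted p = 0.0234), whose call ended without solvent replicate 2 or 5 or 3.33 µg/g replicate 3 (up to 0.0672) or with a replicate block (0.0701). The C1QB call also ended in the fit to 2 groups (0.0603). Endoplasmic reticulum stress rose (median 0.30, adjusted p = 4.66e-05; adjusted p = 0.396 with an estimated correlation) with 0 genes passing over all genes and 1 over the list alone. Cholesterol synthesis rose (median 0.22, adjusted p = 0.0291; adjusted p = 0.530 with an estimated correlation) with 0 genes passing by either adjustment. The cholesterol call ended without solvent replicate 3 or 4 or 3.33 µg/g replicate 1 or 3 (adjusted p up to 0.233). NCOA1 (0.67, SE 0.12, adjusted p = 0.0107) and HSD17B12 (0.49, SE 0.08, adjusted p = 0.00690) rose as single members of their lists, and CUBN averaged 3.52 ± 1.93 CPM against 0.422 ± 0.291 CPM (3.06, adjusted p = 0.0518). CUBN passed without 3.33 µg/g replicate 5 or 33.3 µg/g replicate 1, 2 or 4 (adjusted p down to 0.0289).

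Glucose metabolism fell as a set at 3.33 µg/g (median −0.27, adjusted p = 0.000676; adjusted p = 0.0602 with an estimated correlation). Over all genes 0 of 15 passed, and 4 fell adjusted over the list alone. G6PC, the last step of glucose release, was at 386 ± 76.3 CPM against 608 ± 65.1 CPM (−0.65, SE 0.16, adjusted p = 0.0515). The glucose transporter gene SLC2A2 was at 283 ± 41.1 against 445 ± 73.6 CPM (−0.66, SE 0.16, adjusted p = 0.0551). G6PC passed without 3.33 µg/g replicate 1 or 5 or 33.3 µg/g replicate 3 or 5 (adjusted p down to 0.0245), and SLC2A2 without 33.3 µg/g replicate 5 (0.0303). Hepatocyte plasma proteins fell (median −0.34, adjusted p = 8.33e-05; adjusted p = 0.530 with an estimated correlation) with 0 of 27 genes passing by either adjustment. In 3.33 µg/g replicate 4, the library with the lowest albumin share, the list score was 8.87 mean log2 CPM against a mean of 9.63 in the other libraries of its dose. Cell cycle (median −0.18, adjusted p = 0.000159), acute phase and interferon response (median −0.66, adjusted p = 0.0112) and apolipoproteins (median −0.44, adjusted p = 0.0452) fell too, although APOB, the 1 of 16 apolipoprotein genes that passed, rose. With an estimated correlation these lists had adjusted p = 0.634, 0.614 and 0.396. Adjusted over the list alone, 0 cell cycle genes changed, 2 acute phase genes fell, and 2 apolipoprotein genes rose and 4 fell. The cell cycle call ended without 3.33 µg/g replicate 2 (0.0684), and the acute phase call without solvent replicate 5 or 3.33 µg/g replicate 2 (up to 0.549). The apolipoprotein call ended without solvent replicate 3 or 5 or 3.33 µg/g replicate 2 or 4 (up to 0.172). It also ended with a replicate block (0.0818), with at least 10 counts in every library of a group (0.0506) and without the 2 libraries of low albumin share (0.0885).

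At 3.33 µg/g, 200 genes passed in edgeR, 155 higher and 45 lower, and 2121 had an unadjusted p under 0.05 where chance gives 725. The median log2 fold change was 1.49 among genes that rose and −0.68 among those that fell, and 37 of the 200 genes have only a locus number or no symbol. The count was 111 without solvent replicate 1, with 95 higher, and 117 without 3.33 µg/g replicate 3, with 101 higher. The number lower was 16 without solvent replicate 1 or 3.33 µg/g replicate 3 or 4, 29 without solvent replicate 2 and 74 without 3.33 µg/g replicate 1.

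**Figure D3:**
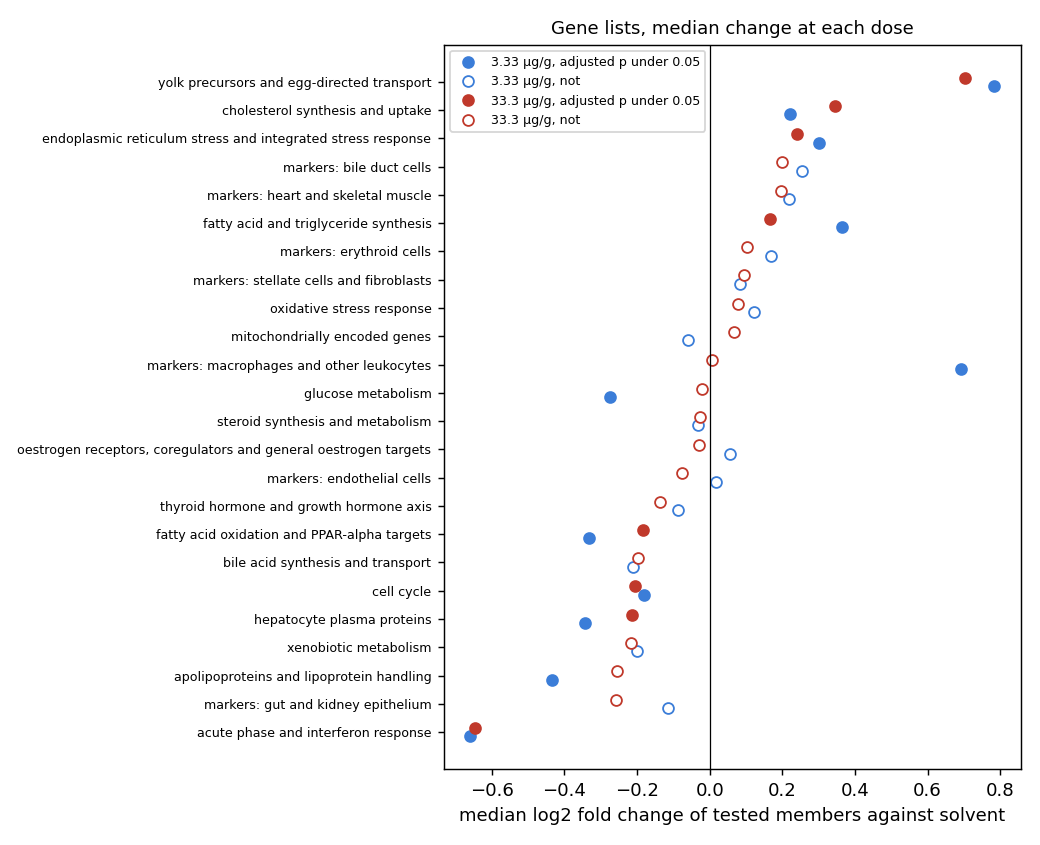
Median log2 fold change against solvent of the tested members of 24 gene lists, blue for 3.33 and red for 33.3 µg of ethinylestradiol per g of egg; filled points had an adjusted p under 0.05 in camera with a preset correlation. The yolk precursor list stood at 0.78 and 0.70, and macrophage markers at 0.69 and 0.01.

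The other lists did not pass against solvent at either dose in camera with the preset correlation. Adjusted p at 33.3 and 3.33 µg/g was 0.760 and 0.651 for oestrogen receptors and coregulators, 0.292 and 0.530 for bile acid synthesis and transport, 0.126 and 0.0983 for xenobiotic metabolism and 0.692 and 0.682 for steroid synthesis. It was 0.470 and 0.794 for the thyroid and growth hormone axis, 0.3925 and 0.750 for oxidative stress, and 0.337 and 0.404 for mitochondrially encoded genes. Among markers of other cell types it was 0.924 and 0.530 for erythroid cells, 0.0993 and 0.672 for endothelial cells, and 0.517 and 0.403 for stellate cells and fibroblasts. It was 0.869 and 0.483 for bile duct cells, 0.869 and 0.750 for heart and skeletal muscle, and 0.608 and 0.891 for gut and kidney epithelium. At 33.3 µg/g it was 0.760 for macrophages, 0.480 for glucose metabolism and 0.517 for apolipoproteins. Of the pancreas markers only 3 were tested, too few for the set test, and 0 of these passed over all genes. At 33.3 µg/g the median, mean and test differed in sign for oestrogen receptors (median −0.03, mean 0.12, test upward), steroid synthesis (−0.03, −0.12, upward), glucose metabolism (−0.02, 0.02, downward), erythroid markers (0.10, 0.02, downward) and gut markers (−0.26, 0.12, downward). At 3.33 µg/g they differed for steroid synthesis (−0.03, −0.01, upward) and gut markers (−0.11, 0.18, upward). By the mixed test of fry 10 of 24 lists passed at 33.3 µg/g and 13 at 3.33 µg/g. Among them were oestrogen receptors (adjusted p = 0.000144 and 2.25e-05), steroid synthesis (0.000241 and 0.000292) and oxidative stress (0.00760 and 0.00821). The thyroid axis passed it at 3.33 µg/g (0.00197) and apolipoproteins at 33.3 µg/g (2.92e-05). A list that did not pass in camera can thus hold changed members.

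Between the doses no gene passed. HARBI1 was at 28.1 ± 6.14 CPM at 33.3 µg/g and 15.4 ± 1.91 CPM at 3.33 µg/g (log2 fold change 0.87, SE 0.13, adjusted p = 0.0912). TMEM192, a lysosomal membrane gene, was at 9.9 ± 0.536 and 16.2 ± 2.55 CPM (−0.71, SE 0.11, adjusted p = 0.0912). CGN (0.55, adjusted p = 0.242), ZNF395 (0.73, adjusted p = 0.258) and MFN1, of mitochondrial fusion (0.50, adjusted p = 0.314), followed. Each of these 5 genes had 5 of 5 libraries of 1 dose beyond every library of the other. Their choice by the smallest p among genes with a symbol favours such a separation. The yolk list genes differed by −0.21 (APOB, adjusted p = 0.947), −0.08 (RBP4, adjusted p = 0.986), −0.76 (ZP1, adjusted p = 0.967), 0.32 (MTTP, adjusted p = 0.877) and 0.37 (TF, adjusted p = 0.947). In edgeR 0 of 14508 genes passed and 805 had an unadjusted p under 0.05 where chance gives 725; DESeq2 called 19 genes and limma-voom 0. Of genes simulated with a 4-fold difference between the doses 90.9% were recovered, and of those with a 1.5-fold difference 29.9%.

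Camera with the preset correlation called 6 gene lists between the doses, where no single gene passed. Chance cannot be excluded for this number of lists: 47 of 100 splits of the treated libraries, the real one included, gave as many. With fry 0 lists passed. Macrophage and leukocyte markers were lower at 33.3 than at 3.33 µg/g (median −0.58, 13 of 14 values below 0, adjusted p = 5.66e-09; adjusted p = 0.269 with an estimated correlation). CSF1R was at 9.47 ± 1.18 and 16.8 ± 8.34 CPM and C1QB at 8.37 ± 1.14 and 14.9 ± 4.02 CPM. In 3.33 µg/g replicate 3 CSF1R was at 31.4 CPM against 10.4 to 14.8 CPM in the other libraries of that dose, and C1QB at 21.9 against 11.6 to 14.2 CPM. Endothelial markers were lower (median −0.14, adjusted p = 0.00186; adjusted p = 0.715 with an estimated correlation), with STAB1 at 90.2 ± 7.38 and 126 ± 29.7 CPM. Glucose metabolism was higher (median 0.15, adjusted p = 0.000939; adjusted p = 0.130 with an estimated correlation), with G6PC at 565 ± 123 and 386 ± 76.3 CPM. Cholesterol synthesis (median 0.17, adjusted p = 0.00166), fatty acid oxidation (0.13, adjusted p = 0.0129) and mitochondrially encoded genes (0.14, adjusted p = 0.00227) were higher as well; with an estimated correlation these had adjusted p = 0.660, 0.861 and 0.861. Over all genes 0 members of these 6 lists passed; adjusted over the list alone 4 macrophage and 1 endothelial markers were lower and 2 glucose genes higher. The cholesterol call ended without 33.3 µg/g replicate 2 (0.108), and the mitochondrial call without 3.33 µg/g replicate 4 (0.402). The fatty acid oxidation call ended without 3.33 µg/g replicate 3 or 4 or 33.3 µg/g replicate 3, 4 or 5 (up to 0.512) and with the chromosome Z covariate (0.0978). The median, mean and test differed in sign between the doses for 8 lists that did not pass: yolk precursors, oestrogen receptors, plasma proteins, thyroid axis, cell cycle, endoplasmic reticulum stress, oxidative stress and acute phase.

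Across the ordered doses, 11 genes had a trend by edgeR, all upward, with 1436 at an unadjusted p under 0.05 where chance gives 725. A slope on dose rank also passes where both doses stand similarly above solvent. A trend here therefore does not show a rise between the doses, where no gene passed. CEBPB, a transcription factor of hepatocytes, stood at 73.9 ± 5.86, 176 ± 9.85 and 191 ± 33.9 CPM with solvent, 3.33 and 33.3 µg/g (log2 change per dose rank 0.69, SE 0.11, adjusted p = 0.0318). FKBP5, a co-chaperone of steroid receptors, stood at 10.3 ± 1.64, 18.3 ± 4.36 and 24.2 ± 5.4 CPM (0.62, SE 0.10, adjusted p = 0.0318). LARP1, which binds messenger RNA, was at 321 ± 13.2, 380 ± 30.1 and 448 ± 28.7 CPM (0.24, SE 0.04, adjusted p = 0.0318). ATP6V0A1 (0.30), HARBI1 (0.49), PIGC (0.44), MIDN (0.53) and CDIP1 (0.35) also had trends, with 3 loci without a gene name. HARBI1 stood at 14.25 ± 0.812, 15.4 ± 1.91 and 28.1 ± 6.14 CPM, with little change from solvent to 3.33 µg/g. The count was 0 without any 1 of the 5 solvent libraries or without 33.3 µg/g replicate 3 or 5. It was 6 without 3.33 µg/g replicate 5 or 33.3 µg/g replicate 1, 2 without 33.3 µg/g replicate 2, 47 without 3.33 µg/g replicate 4 and 107 without 33.3 µg/g replicate 4.

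Of 252 genes that passed at either dose, 105 passed at both, 97 higher at both and 8 lower at both. Of these genes 52 passed only at 33.3 µg/g and 95 only at 3.33 µg/g. Independent lists of these sizes would share 1.45 genes higher and 0.07 lower. Across all 14508 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.804 and Spearman's rho 0.631. Both doses were set against the same solvent libraries. Unchanged groups were therefore simulated together with shared solvent libraries, all drawn from the mean solvent levels. They gave a mean r of 0.509 (range 0.485 to 0.542 over 20 runs), a mean rho of 0.461 and 0 shared genes. Genes were drawn independently, so neither correlation between genes nor the difference of solvent replicate 3 was simulated. The observed covariance was 0.212 and the simulated 0.0490, a difference of 0.163. With solvent libraries split so that the doses shared none, mean r was 0.519, mean covariance 0.176 and the mean number of shared genes 21.1 higher and 0.4 lower. Fewer genes passed with so few solvent libraries, a mean of 50.05 at 33.3 µg/g and 62.5 at 3.33 µg/g, and independent lists of these sizes would share 0.127 genes higher. Mean rho was then 0.273 (range 0.202 to 0.321). The sign was shared by 74.2% of all genes as observed, 66.8% in the simulated unchanged groups and 59.9% with split solvent libraries.

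**Figure D4:**
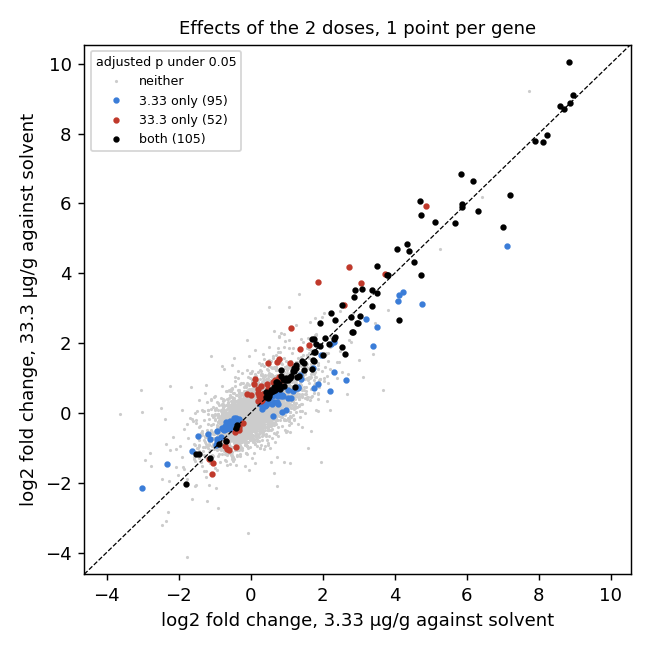
Log2 fold change against solvent of each tested gene at 33.3 µg/g (vertical axis) and 3.33 µg/g (horizontal axis); black points passed at both doses, blue only at 3.33 µg/g, red only at 33.3 µg/g, and the dashed line marks equal change. Of the 252 genes that passed at either dose, 105 passed at both, 97 of them higher and 8 lower.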

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

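The tests on solvent replicate 3, on ZP1 in that library and on the 2 libraries of low albumin share were chosen after these results were seen. An earlier form of the albumin tests took both libraries together, and its depth test, whether these were the smallest of their doses (1 of 2 was), was replaced after it had been seen. The tests of power and of other groupings of the libraries were fixed earlier.

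Transcripts induced by ethinylestradiol were present at a low level in solvent replicate 3. Over 31 genes raised more than 8-fold at both doses the summed level was 553.6 CPM there, 35.4 to 74.7 CPM in the other solvent libraries and 7409 CPM or more in every treated library. LOC107317565 had 435, 370, 26 and 51 counts in solvent replicates 1, 2, 4 and 5, and LOC107319873 had 374, 314, 8 and 10. LOC107317352 had 78, 103, 4 and 6, so these loci were also higher in replicates 1 and 2 than in 4 and 5. NPTXR, also raised by treatment, had 37, 28, 26 and 22. Replicates 1 and 2 were part of the baseline for the excess given below, and the cause of their levels was not tested. A treated embryo under a solvent label is argued against: over 53 genes changed at both doses and at 5 CPM or more with solvent, the median position of this library between the other solvent libraries (0) and the treated libraries (1) was 0.005. These genes were called with this library counted as solvent, which favours a low position, so the value alone does not exclude such an embryo. Reads carried over from treated libraries could account for 10 of the 11 genes of this set in excess there, all 11 being at a median level of 1.61% of the treated mean; 1, a locus without a gene name, made up a share of the excess outside its range in the treated libraries, and with so few genes carry-over cannot be told apart from a weak response. ZP1, in a set widened after the first count to genes called at 1 or both doses (39 genes, 13 in excess, 2 outside), argues against carry-over for itself: it made up 7.89% of the excess (99% counting interval 7.21% to 8.62%) against 0.260% to 1.25% in treated libraries. A weak exposure stays open, untested.

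ZP1 stood at 45.1 CPM in solvent replicate 3 against 1.45 to 3.06 CPM in the other solvent libraries, and at 365 CPM in 3.33 µg/g replicate 3 against 134 to 158 CPM. The score of the yolk precursor list was 10.18 mean log2 CPM in solvent replicate 3 against 9.24 to 9.37. AANAT was at 0.0475 CPM in solvent replicate 3, from 1 count, and at 0 in the other solvent libraries. In the same library MFN1 was at 44.9 CPM against 59.1 to 61.5 CPM, the cell cycle score was 5.47 against 5.81 to 5.94, and the endoplasmic reticulum stress score was 6.57 against 6.92 to 7.003.

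Albumin took 4.85% of the counts in 3.33 µg/g replicate 4, against 9.71% to 11.6% in the other libraries of that dose, and 5.87% in 33.3 µg/g replicate 1, where the plasma protein score was 8.93 against 9.57 to 9.78. Lower depth is argued against: the library with the nearest total held 13.3% albumin for the first and 9.97% for the second. On TMM-scaled scores, fewer hepatocytes and more of the other cell types is argued against for 3.33 µg/g replicate 4. There 2 of 5 lists of other cell types, endothelial (−0.21) and stellate (−0.36), lay below the other libraries of the dose by more than their SD. Bile duct markers (0.45) lay above by more than theirs, so that a change in those cells stays open. The TMM factor of this library, 1.196, was the highest and lowers all its scores relative to library totals, so fewer hepatocytes cannot be excluded for it. For 33.3 µg/g replicate 1 the count of lists below by more than the SD was 0. All 5 lay above, so that fewer hepatocytes may account for its lower albumin share. A difference in developmental stage or in the part of the lobe sampled was not tested.

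Other libraries far from the rest of their group, with gene levels compared as log2 CPM, were these. SYT12 was at 0.491 CPM in 3.33 µg/g replicate 1 against 0.935 to 1.204 CPM. In 3.33 µg/g replicate 4, TMEM181 was at 58.6 CPM against 102 to 126 CPM, MIDN at 55.4 CPM against 33.6 to 38.8 CPM and SUN2 at 110 CPM against 58.2 to 69.5 CPM. CBX6 was at 63.9 CPM in 33.3 µg/g replicate 1 against 42.9 to 47.4 CPM. In solvent replicate 4, AGPAT2 was at 42.9 CPM against 30.4 to 33.2 CPM, LPIN1 at 4.38 CPM against 3.28 to 3.40 CPM, and the erythroid marker score at 4.11 against 3.66 to 3.71. In 33.3 µg/g replicate 4, HERPUD1 was at 17.2 CPM against 26.5 to 29.3 CPM and the endoplasmic reticulum stress score at 6.91 against 7.21 to 7.31. The mitochondrial score was 11.34 in 33.3 µg/g replicate 1 against 11.76 to 11.85, and the endothelial score 4.69 in 33.3 µg/g replicate 3 against 4.86 to 4.92. The heart and muscle score was 3.37 in 3.33 µg/g replicate 2 against 1.51 to 1.60. Of 294 groups of 5 tested in this way 22 were singled out, and chance gives 14.7.

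The doses differed by the test of their difference in 6 gene lists: cholesterol synthesis (adjusted p = 0.00166), fatty acid oxidation (0.0129), glucose metabolism (0.000939), mitochondrially encoded genes (0.00227), endothelial markers (0.00186) and macrophage markers (5.66e-09). None of the 6 passed with an estimated correlation or with fry (0 lists each). Chance cannot be excluded for this count, since 47 of 100 splits of the 10 treated libraries gave as many lists, up to 11 in the other splits with a median of 5. For genes of ordinary spread, a lack of power for changes of 4-fold does not explain that no single gene passed between the doses. In simulated data 90.9% of such changes were recovered, in genes drawn at random from all those tested. Power for the induced genes, many of which varied widely between libraries, was not simulated apart, so 4-fold differences in them stay open. For changes of 1.5-fold, with 29.9% recovered, a lack of power may hide differences. A count of 0 genes is matched by all 100 splits whatever the cause, up to 12 in the other splits, and this decides nothing.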

How the results depend on the processing

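The setting without the 2 libraries of low albumin share was chosen after the data were seen. No named gene called against solvent, and no list that was called, turned its direction under the settings run for it; genes not named and trend genes were not followed. Against solvent, RLE factors, library totals, both low-count filters, both covariates, the fit to the 2 groups, limma-voom and the setting without the libraries of low albumin share (152 genes at 33.3 µg/g and 155 at 3.33 µg/g) left the counts within 1.5 times. At 33.3 and 3.33 µg/g the counts were 101 and 117 with a replicate block, 97 and 110 with an absolute log2 fold change of at least 1 and 248 and 468 at an adjusted p under 0.1. They were 395 and 653 with DESeq2, which kept 157 of the 157 and 199 of the 200 genes. With 1 library left out they ran from 93 to 194 and from 111 to 264. Between the doses the count was 2 at an adjusted p under 0.1, 19 with DESeq2 and 0 with any 1 library left out. The trend count, 11, was 0 with library totals, 5 with no low-count filter, 1 with a replicate block, 4 with the erythroid covariate, 49 with the chromosome Z covariate and 2 with a log2 change of at least 1 per dose rank. It was 103 at an adjusted p under 0.1, 3 with limma-voom, 278 with DESeq2, 27 without the libraries of low albumin share and 0 to 107 with 1 library left out. Lists called at 33.3 µg/g, at 3.33 µg/g and between the doses numbered 2, 1 and 0 with an estimated correlation and 3, 3 and 0 with fry, and with 1 library left out 8 to 9, 8 to 11 and 4 to 9. The correlation of the dose effects was 0.519 with split solvent libraries, which removes the shared libraries and also leaves 2 or 3 solvent libraries per dose. Looser and stricter thresholds change the counts by construction; otherwise the cause was not tested. Of the named genes called, 19 of 41 at 33.3 µg/g and 17 of 43 at 3.33 µg/g lost the call with at least 1 library left out. At 33.3 and 3.33 µg/g 16 and 13 lost it with limma-voom, 13 and 14 with a replicate block, 10 and 6 without the libraries of low albumin share, and 8 of 40 and 6 of 39 in the fit to 2 groups. Genes lower numbered 40 and 96 with the chromosome Z covariate and 113 and 243 with DESeq2, 32 and 56 with library totals, 7 and 14 with a replicate block and 17 and 26 without the libraries of low albumin share, against 21 and 45. The fit to only 2 groups has no meaning for the trend, and settings for TPM were not run because the file holds estimated counts. At these depths, with 5 libraries per group, 29.9% to 37.3% of simulated changes of 1.5-fold were recovered; other depths were not simulated.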

Other observations

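The permutation test of neighbouring genes was chosen after the result was seen; the tests of other groupings of the libraries were fixed earlier.

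Genes raised by ethinylestradiol lay beside each other. On the reference assembly the order CBX6, NPTXR, DNAL4, a locus without a gene name and SUN2 is unbroken among the genes tested. All 5 rose at both doses (log2 fold changes at 33.3 µg/g of 0.69, 6.25, 1.04, 8.88 and 1.91). KIF3C (2.18), the vesicle transport gene RAB10 (1.0) and GAREM2 (5.46) were adjacent and rose, as did the pair LY75 (1.96) and PLA2R1 (1.44), both of the mannose receptor family, and the pair PIGC (0.89) and SUCO (1.04). SSX2IP (1.29), LOC107317565 (7.76), SPATA1 (4.65), the G protein subunit gene GNG5 (0.70) and DNASE2B (1.98) lay close together.

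Of 185 raised genes placed on a chromosome, 63 had another raised gene within 3 tested genes, against a mean of 14.7 and a highest of 36 in 10000 random placements (one-sided permutation p = 1e-04, the smallest these can give). The reason for this placement was not tested.

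Other splits of the 10 libraries of a comparison into groups of 5 bear on the counts of genes. The remaining group was left unchanged in these fits, and 100 of 126 splits were fitted. For 33.3 µg/g against solvent, 1 of 100 splits, the real one, gave 157 genes, and the highest other gave 1. For 3.33 µg/g, 1 of 100 gave 200 genes, and the highest other gave 1. This argues against chance for both counts, although 1 of 100 is the smallest share these splits can give. For the trend 2 of 100 orders of the 15 libraries, the real one included, gave 11 genes or more. By the share fixed beforehand this argues against chance for the count. Random orders mix all groups, so this bears on any difference between them and not on a rise from dose to dose. The highest other order gave 152 genes, many times the real count, with a median of 0 over the other orders. What set that 1 order apart was not tested. For the number of lists called by camera with the preset correlation, chance cannot be excluded. At 33.3 µg/g 17 of 100 splits gave 8 or more lists, up to 12 in the others with a median of 5. At 3.33 µg/g 5 of 100 gave 11 or more, up to 12 in the others with a median of 6. The splits bear on this number and not on any 1 list. With an estimated correlation the yolk precursor list passed at 33.3 and 3.33 µg/g (adjusted p = 0.00227 and 0.0133). That list also passed with fry (8.84e-05 and 0.000248).

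The mean level of 645 genes of chromosome Z was 3.08 to 3.16 log2 CPM in 1 solvent library, 2 libraries at 3.33 µg/g and 1 at 33.3 µg/g, and 3.43 to 3.61 log2 CPM in the other 11 libraries. The labels do not give the sex of the embryos, and the reason for the lower level was not tested. With this mean as a covariate, 208 genes passed at 33.3 µg/g and 288 at 3.33 µg/g against solvent.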
